A study of Bos taurus with 10 samples.

How the data were processed

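Sperm RNA was extracted with the miRNeasy Mini Kit and made into small RNA libraries with a NEBNext kit for Illumina sequencing, per the labels' protocols. Trimmomatic 0.39 and DESeq2 1.34.0 are named in the submitters' processing notes, without their roles. The aligner, genome build, miRNA and tRNA annotation and counting rules are not given in the sources used here, so no coordinates are printed. Nothing states how reads that fit several near-identical tRNA or miRNA entries were counted.

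The 3 tables hold the authors' own comparisons and group values. The 2 miRNA tables give, per the file headers, a signal (the mean of size-factor normalized counts over the samples of the comparison), a log2 fold change with its standard error, a Wald statistic (a score), a p-value and an adjusted p-value for each miRNA, all by the authors. From the values, the deposited adjusted p is the Benjamini-Hochberg adjustment over all rows with a p: recomputing it gave a largest difference of 5.98e-14. The tsRNA table gives, per the file headers, a log2 fold change and an unadjusted p-value for each comparison and 1 normalized signal per group. Every positive group value was a whole multiple (tolerance 1e-04) of 1 of 3 steps, and high bull fertility values equalled high daughter values in 1902 rows and low daughter values in 4853 rows, as medians over 3 libraries do where groups share a library. Each row shows 1 library per group, so whole reads could not be recovered per sample.

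Count-based tests had been planned before the data were examined. They were replaced by the values of the authors' deposited tables, since no per-sample values were at hand. The overlap of groups in named features, which the rule asked to be stated, cannot be seen from these values. For the same reason no sample could be left out, no labels permuted, no counts summed per family, and no set test with an estimated correlation run. Fragment lengths were not analysed here. A refit to set against the authors' fold changes could not be made either.

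The header of the miRNA tables does not name the numerator of the fold change. The means of miR-2285ab and miR-2285dc stood in the same ratio, 1.137, between the 2 tables, as they would if all their reads lay in a library that both comparisons share. Both shared libraries are high bull fertility, and both deposited fold changes for bull fertility are negative (-1.27 and -3.07), so the deposited sign is low over high. For daughter fertility the same 2 miRNAs have deposited fold changes of -2.33 and -3.81. Which of the shared libraries holds their reads is not settled. At 1 read for miR-2285ab its size factor is 0.704 in the bull and 0.619 in the daughter fertility table, near the 0.618 of the library labelled high bull and high daughter fertility in the tsRNA table. At 2 reads it is 1.41 and 1.24, near the 1.39 of that labelled high bull and low daughter fertility, so these miRNAs do not fix the daughter fertility sign. The argument for it rests on depth alone: 8 miRNAs with reads in 1 unshared library carry a positive deposited sign, and that library's size factor of 1.85 is nearer to the deepest low daughter fertility library of the tsRNA table (2.21) than to the high ones (0.618 to 0.785). All miRNA signs were turned to high over low. The signs of the tsRNA fold changes are given by the column names and were the same as those of the group values in 79.2% and 77.3% of rows with a mean of at least 10.

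The threshold was an adjusted p under 0.05. For tsRNAs the Benjamini-Hochberg adjustment was computed here over all rows with a p, and the standard error of a tsRNA fold change was derived from the authors' fold change and p. tRNA fragment families combined isotype, anticodon and fragment type among entries with the tRNA prefix, each represented by its most abundant row with a mean group value of at least 10. The named miRNAs followed a rule fixed before the data were examined: per comparison, up to 10 per direction past the threshold with a mean of at least 10, filled up to 5 per direction by smallest p, plus the 10 most abundant and up to 4 per fixed list. For tsRNAs the numbers were 8 and 4, plus the 5 most abundant rows and families. The unit of counts scaled to library size in that rule became the authors' mean normalized count, and tRNA and tRX entries were taken apart. The text gives the leading items of each group.

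List medians were compared with 10000 random lists drawn from the 50 miRNAs nearest in abundance to each member. For the concordance, 100 sets of 10 libraries with no effect were simulated with the depths read from the tsRNA table and the authors' means and standard errors, with a pseudocount of 0.5. miRNA genes were matched by name to the RefSeq annotation of ARS-UCD2.0, for neighbours alone, and 908 of 978 names matched 1 gene. Routines were tested on simulated data, and all 3 steps were recovered in 20 of 20 draws over 184397 rows. For the Benjamini-Hochberg routine, normal scores were drawn for 978 rows, as many as in the daughter fertility miRNA table, with 200 shifted far. A share of 0.992 of these was found, with a share of 0.0358 false calls. No counts or spread of the samples entered, so this does not measure the power of these comparisons. Alternatives were a threshold of 0.1, minimum means of 10 and 100, p-values taken from the Wald statistic where missing, tRNA entries alone, the median statistic of a family, and group medians in place of model fold changes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.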

Results

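Small RNA was sequenced from bull sperm to ask which microRNAs (miRNAs) and tRNA-derived small RNAs (tsRNAs) differ with the fertility of the bull or of its daughters. The 10 samples gave 3 with high and 3 with low bull fertility, and 3 with high and 3 with low associated daughter fertility. 2 samples carried both labels: each counted as high bull fertility, and they fell on opposite sides of the daughter fertility comparison. The labels do not say that the samples came from separate bulls, so the p-values below measure only the spread between these samples. Fold changes and p-values, and for miRNAs the standard errors (SE), are the authors' own. Those for miRNAs rest on the 6 samples of each comparison. For tsRNAs the standard errors implied by the p were nearly equal in both comparisons, such as 0.683942 and 0.683941 for 5′ Gly-GCC. A joint fit over all groups would give this, so tsRNA p-values may draw on samples outside their comparison. Such a fit may also have entered the 2 samples with both labels more than once. The group values of the tsRNA table behaved as medians over the 3 libraries of a group, and carry no spread. All fold changes are written as high over low fertility. For miRNAs the direction was inferred from the values, firmly for bull fertility and less firmly for daughter fertility. Every miRNA direction given for daughter fertility rests on that inference.

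Depth could be read from the tsRNA values, since each was a whole multiple of what 1 read was worth in a library. By the authors' deposited table, 1 read stood for 0.453 to 1.62 normalized counts, depending on the library. Relative depth ran from 0.618 to 1.39 reads per normalized count with high bull fertility and from 0.945 to 1.89 with low bull fertility. With high daughter fertility it ran from 0.618 to 0.785, and with low daughter fertility from 0.903 to 2.21, so these ranges did not overlap. Total reads per library are unknown here. The group values held 24429 rows above 0 for high bull, 28253 for low bull, 21659 for high daughter and 38534 for low daughter fertility.

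**Figure D1:**
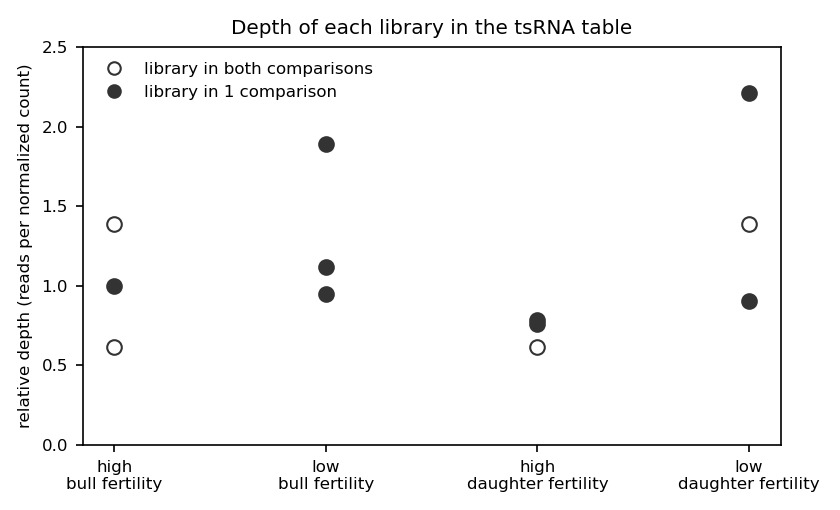
Relative depth (reads per normalized count, vertical axis) of the 3 libraries of each group (horizontal axis) in the tsRNA table, with open circles for the 2 libraries that enter both comparisons. The low daughter fertility libraries lie between 0.903 and 2.21, above the high daughter fertility libraries at 0.618 to 0.785.

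Abundant miRNAs of the sperm libraries included miR-375, miR-100, miR-12030, miR-10b and miR-34c, which is enriched in male germ cells. In the authors' deposited tables miR-375 had a mean normalized count of 6860 in the bull fertility comparison and 7694 in the daughter fertility comparison, which was 6.19% and 5.35% of the summed means. The values for miR-100 were 2494 and 6411, and those for miR-12030 were 3641 and 3340. Means of 1914 and 2442 were given for miR-34c in the authors' deposited tables. The 10 most abundant miRNAs of each table together held 22.1% and 22.3% of the summed means. Of the 978 listed miRNAs, 867 and 882 had a mean of at least 10.

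No miRNA passed the threshold for bull fertility. The smallest p-values in the authors' deposited table were those of members of the cattle miR-2284 and miR-2285 family: miR-2285cp was 4.76 log2 units higher with high bull fertility (SE 1.26), and miR-2285cn 3.13 higher (SE 0.92). Next by p among those higher with high bull fertility were miR-2322-3p at 2.10 (SE 0.67), miR-365-3p at 2.02 (SE 0.69) and miR-216a at 1.61 (SE 0.58) in the authors' deposited table. On the lower side of the authors' deposited table, miR-98, a let-7 family member, had a log2 fold change of -2.51 (SE 0.89). There, miR-656 stood at -1.27 (SE 0.47), miR-2891 at -1.93 (SE 0.74), miR-562 at -2.08 (SE 0.81) and miR-2377 at -3.62 (SE 1.46). None of these passed: the smallest Benjamini-Hochberg adjusted p of the authors' deposited table, from the authors' Wald test, was 0.163, for miR-2285cp. Unadjusted p was under 0.05 for 45 of 964 miRNAs, 28 higher and 17 lower with high bull fertility, against 48.2 expected by chance.

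Of the abundant miRNAs in the authors' deposited table for bull fertility, miR-375 had a log2 fold change of 0.29 (SE 0.43), miR-100 of 0.16 (SE 0.69), miR-10b of 0.13 (SE 0.54), miR-432 of 0.07 (SE 0.41), miR-2284x of 0.22 (SE 0.43) and miR-12058 of 0.10 (SE 0.54). For miR-11980 it was -0.04 (SE 0.51), for miR-12030 -0.72 (SE 0.68) and for miR-186 -0.76 (SE 0.54) in the authors' deposited table. Germ-cell-enriched miR-34c was 2.53-fold lower with high bull fertility there, with an unadjusted p of 0.104 in the authors' deposited table, and so not past the threshold.

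2 miRNAs passed the threshold for daughter fertility, both lower with high daughter fertility by the inferred direction. For miR-323b-3p the authors' deposited table gave a log2 fold change of -3.57 (SE 0.80), with a mean normalized count of 420.0 and a Benjamini-Hochberg adjusted p of 0.00724. The gene of miR-323b-3p neighbours those of 50 other measured miRNA names in a large cluster that includes miR-656 and miR-495. For miR-11999 the authors' deposited table gave -2.11 (SE 0.52), a mean of 136 and an adjusted p of 0.0277. Also listed in the authors' deposited table is let-7a-5p at -5.37 (SE 1.45) with an adjusted p of 0.0674, which is past 0.1 and not past 0.05. Its mean was 36.3, against 4.39 in the bull fertility comparison, which holds 1 library of each daughter fertility group. The authors marked these 3 miRNAs as upregulated, with a positive deposited fold change, which by the inferred direction means higher with low daughter fertility. In the bull fertility comparison miR-323b-3p was listed at -2.34 (SE 0.83) without a p, in the authors' deposited table. An adjusted p was likewise missing for 26 miRNAs of the daughter fertility table that have a test statistic, 24 of them lower with high daughter fertility. Why is not stated in the sources used here. A p computed from their Wald statistic, as in an alternative below, may thus restore rows that the authors' test set aside.

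Short of the threshold, miR-10183-5p stood at -2.68 (SE 0.78) and miR-4523 at -1.99 (SE 0.66) in the authors' deposited table. On the higher side of the authors' deposited table were miR-147 at 2.17 (SE 0.69), miR-6119-5p at 1.80 (SE 0.58), miR-2285d at 2.42 (SE 0.83), miR-495 at 2.33 (SE 0.83) and miR-2349 at 1.29 (SE 0.50). Unadjusted p was under 0.05 for 58 of 951 miRNAs in the authors' deposited table, 22 higher and 36 lower, against 47.6 expected by chance. Of the 10 most abundant miRNAs, miR-34c stood at 1.33 (SE 0.76), miR-30d at 1.10 (SE 0.64), miR-186 at 1.05 (SE 0.67), miR-12030 at 0.84 (SE 0.73), miR-125b at 0.59 (SE 0.75) and miR-432 at 0.56 (SE 0.90) in the authors' deposited table. Closer to 0 there were miR-2284x at 0.24 (SE 0.52), miR-100 at 0.18 (SE 0.92), miR-10b at 0.16 (SE 0.64) and miR-375 at -0.21 (SE 0.55) in the authors' deposited table.

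**Figure D2:**
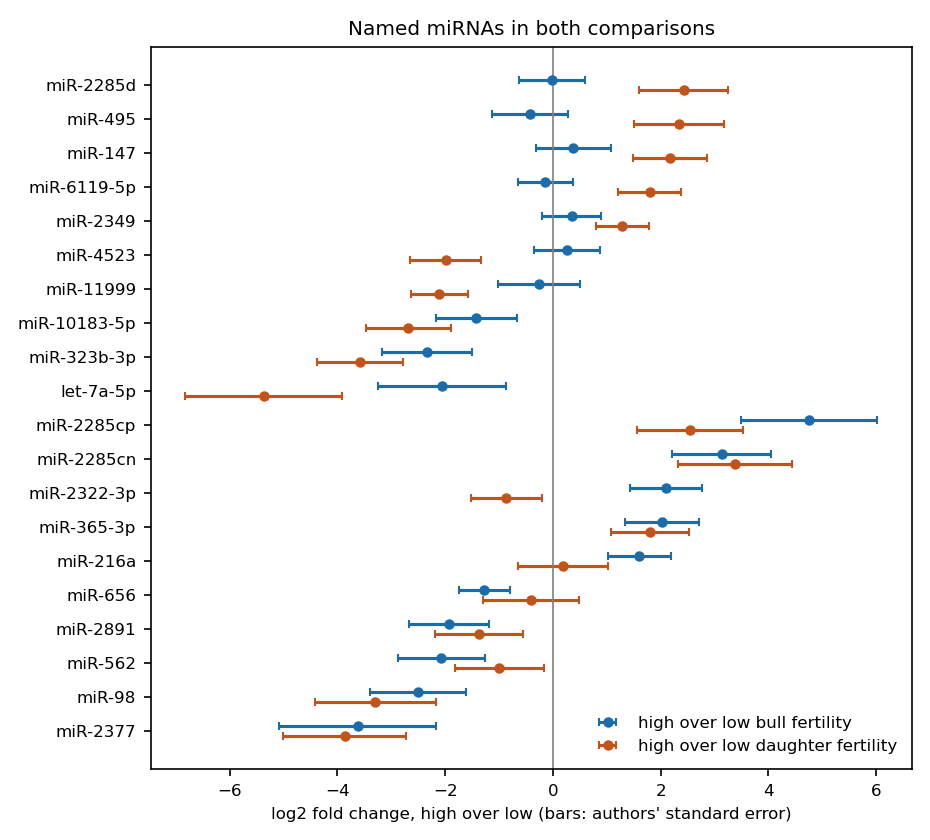
Log2 fold change (horizontal axis, high over low) of the miRNAs with the smallest p in each direction of either comparison (vertical axis), in blue for bull and in orange for daughter fertility, with the authors' standard error as bars. The 2 miRNAs past the threshold are miR-323b-3p at -3.57 and miR-11999 at -2.11 for daughter fertility.

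Of the 12 miRNA families fixed in advance, no member passed the threshold in either comparison when adjusted over all miRNAs. The let-7 family had 9 measured members. Adjusted over the list alone, 1 let-7 member passed for bull fertility (miR-98) and 2 for daughter fertility (let-7a-5p and miR-98). For daughter fertility miR-98 was at -3.30 (SE 1.13), let-7f at 0.99 (SE 0.74), let-7d at 0.41 (SE 0.75) and let-7e at 0.95 (SE 0.71) in the authors' deposited table. Of the 9 let-7 members 6 were higher with high bull fertility and 5 with high daughter fertility, with medians of 0.26 and 0.41. Of the 119 measured miR-2284 and miR-2285 names, 63 were higher and 56 lower with high bull fertility, and 2 passed when adjusted over the list alone (miR-2285cp and miR-2285cn). For daughter fertility 58 of 129 were higher and 71 lower, and 0 passed when adjusted over the list alone. The names measured for daughter fertility alone included miR-2284z, miR-2284y and miR-2285f, each lower and with all reads in 1 library. Another of them, miR-2285ay, was higher at 0.05.

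The other families gave 0 members past the threshold, adjusted over the list alone, in both comparisons. In the miR-17/92 clusters 12 of 15 members were lower with high bull fertility and 12 of 14 were higher with high daughter fertility, with medians of -0.32 and 0.32. With the inferred daughter fertility direction turned, these 12 of 14 would be lower too, as in the bull fertility comparison. The most abundant member of these clusters, miR-25, stood at -0.08 (SE 0.46) and 0.92 (SE 0.67), and miR-18a at -0.18 (SE 0.49) and 1.00 (SE 0.85), in the authors' deposited tables. For the miR-30 family 6 of 7 members were lower with high bull fertility, with a median of -0.46, and the daughter fertility median was 0.38. The abundant miR-30d stood at -0.94 (SE 0.64) and miR-30a-5p at -0.99 (SE 0.53) for bull fertility in the authors' deposited table. Of 8 miR-15 and miR-16 family names 3 were higher with high bull and 5 with high daughter fertility, with medians of -0.52 and 0.30. Among 6 names of the miR-34 and miR-449 family the numbers were 3 and 5, with medians of -0.08 and 0.44, and miR-449a stood at -1.13 (SE 1.47) and 0.87 (SE 0.65) in the authors' deposited tables. Of 8 names of the miR-10, miR-99, miR-100 and miR-125 family 5 were higher in each comparison, with medians of 0.05 and 0.17. The 6 miR-29 names had 2 and 3 higher and medians of -0.15 and 0.33. All 3 names of the miR-148 and miR-152 family were higher with high bull fertility and all 3 lower with high daughter fertility, with miR-148b at 0.36 (SE 0.42) and -0.57 (SE 0.49) in the authors' deposited tables. Of 4 miR-181 names 3 and 2 were higher, with medians of 0.28 and 0.34. The 6 names of the miR-23, miR-24 and miR-27 clusters had 2 and 3 higher and medians of -0.23 and -0.21, and the 1 measured miR-26 name, miR-26b, stood at 0.78 and 0.99 in the authors' deposited tables. Against 10000 random lists matched on abundance, 0 of the family list medians lay outside the central 95%.

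miRNAs known as markers of other cells, which bulk libraries can hold, did not pass the threshold in either comparison when adjusted over all miRNAs. The leukocyte list had medians of -0.26 for bull and -0.34 for daughter fertility, with 6 of its 7 members lower with high daughter fertility and 1 past the threshold when adjusted over the list alone. That member, named after its value was seen, was miR-146a at -2.47 (SE 0.84) for daughter fertility in the authors' deposited table. Leukocyte-enriched miR-223 stood at -0.38 (SE 0.49) and -0.66 (SE 0.70) in the authors' deposited tables. All 6 epithelial names were lower with high bull fertility and 4 were higher with high daughter fertility, with medians of -0.18 and 0.23 and miR-200b at 1.67 (SE 0.73) for daughter fertility in the authors' deposited table. The 3 red blood cell names, such as miR-451, had 2 higher in each comparison and medians of 0.18 and 0.12. Of 5 smooth muscle and stroma names, such as miR-143, 2 were higher in each comparison, with medians of -0.37 and -0.18. The 2 endothelial miR-126 names were both higher with high bull and both lower with high daughter fertility (medians 0.49 and -0.29). Of 4 skeletal muscle names 3 and 1 were higher, with medians of 0.73 and -1.24, though the most abundant, miR-206, stood at 0.50 (SE 0.42) and 0.62 (SE 0.61) in the authors' deposited tables. The liver marker miR-122 stood at 0.59 and 0.78. Adjusted over the list alone, 0 members of the epithelial, red blood cell, stroma, endothelial, muscle and liver lists passed, and 0 of the medians lay outside the central 95% of random lists.

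5′ fragments of tRNAs made up most of the tsRNA signal in all 4 groups. By the authors' deposited table they held 50.7% of the summed group values with high bull fertility, 58.4% with low bull fertility, 58.9% with high daughter fertility and 55.7% with low daughter fertility. Fragments of 3′ origin from tRNA entries held 2.62%, 3.59%, 2.94% and 3.45% in that order. Entries with the prefix tRX, used for tRNA-like loci of lower confidence, held 42.8%, 34.2%, 34.5% and 37.3%. Of the tRNA 5′ signal, glycine tRNAs gave 27.6%, 34.7%, 30.0% and 33.7%, glutamate tRNAs 19.8%, 19.3%, 26.8% and 15.6%, valine tRNAs 21.6%, 15.6%, 17.9% and 18.6%, and histidine tRNAs 15.0%, 13.9%, 11.7% and 15.3%. Near-identical rows had near-equal values, such as 56314 for tRNA-Glu-CTC-2 5′ and 56367 for tRNA-Glu-CTC-1 5′ with high bull fertility in the authors' deposited table. Sums over rows may thus hold the same reads more than once, most of all for isotypes with many rows. With 1 value per group these shares could not be tested. Standard errors below are those implied by the authors' tsRNA fold change and p, and were computed here.

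The most abundant fragment, the 5′ end of tRNA-Gly-GCC-1, had a group value of 104369 with high and 209620 with low bull fertility in the authors' deposited table, a log2 fold change of -1.17 (SE 0.68). The 5′ fragment of tRNA-His-GTG-1 stood at -0.48 (SE 0.70), of tRNA-Glu-CTC-2 at -0.49 (SE 0.70), of tRNA-Glu-TTC-1 at -0.36 (SE 0.69) and of tRNA-Val-CAC-2 at -0.03 (SE 0.69), all in the authors' deposited table. The initiator tRNA-iMet-CAT-1 gave -1.51 (SE 0.85) for its 5′ fragment there, with group values of 9421 and 28743 in the authors' deposited table. By p, the leading tRNA fragments lower with high bull fertility in the authors' deposited table included tRNA-Gly-CCC-36 3′ at -2.45 (SE 0.99) and 5′ at -2.04 (SE 0.99), and tRNA-SeC-TCA-1, the selenocysteine tRNA, at -1.51 (SE 0.72) for fragments of neither end. Higher with high bull fertility, with unadjusted p above 0.05, were tRNA-Lys-TTT-2 5′ at 1.59 (SE 0.94) and tRNA-Gln-TTG-2 5′ at 1.36 (SE 0.86) in the authors' deposited table. Among tRX entries the authors' deposited table gave tRX-Cys-NNN-133187 (neither end) at 4.19 (SE 1.30), and tRX-Val-NNN-45 5′ at -3.30 with group values of 6.47 and 244.

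None of these tsRNAs passed for bull fertility. Benjamini-Hochberg adjustment of the p-values of the authors' deposited table left 0 of 98760 rows past 0.05, and unadjusted p was under 0.05 for 246 rows, 167 higher and 79 lower, where 4938 were expected by chance. Of these 246 rows 206 had a mean under 10, with 149 higher and 57 lower. With a mean of at least 10 the numbers were 18 higher and 22 lower, at 100 or more 0 and 8, and among tRNA entries 1 and 11. At 100 or more, 8 of 994 rows for bull and 14 for daughter fertility had p under 0.05, against 49.7 expected by chance. Such p-values run larger than those of a test with no effect. A count of 0 past the threshold therefore does not show that no tsRNA differs. Of the 142 tRNA fragment families, each taken by its most abundant member, 112 were lower and 30 higher with high bull fertility. Some families had equal values in all 4 groups, as they would if they count the same reads. For 3′ Val-TAC and Val-AAC both were 354.446 with high and 468.543 with low bull fertility. The families are thus not independent, and counts of families may hold the same reads more than once. Of the 140 families with a p none passed the threshold (smallest adjusted p 0.996), and 1, the selenocysteine fragments of neither end, had an unadjusted p under 0.05.

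With high daughter fertility, fragments of 3′ origin from tRNAs were lower in 44 of 47 families, with a median log2 fold change of -1.06. The 5′ fragments of tRNAs were lower in 34 of 44 families, with a median of -0.31, and those of neither end in 40 of 51, with a median of -0.43. Taken from the group values in place of the model, 40 of 47, 29 of 44 and 27 of 51 were lower, with medians of -0.53, -0.19 and -0.048. Other tRNA rows with a mean of at least 10 had model medians of 1.18 (antisense), 1.32 (partial precursor) and -0.62 (whole tRNA). For tRX entries that median was 0.15. Among tRNA entries, the leading rows in the authors' deposited table were tRNA-Trp-CCA-1 3′ at -3.74 (SE 1.13), tRNA-Gly-GCC-4 3′ at -3.01 (SE 1.05), tRNA-Thr-TGT-5 3′ at -2.77 (SE 0.98) and tRNA-Ser-GCT-7 5′ at -2.45 (SE 0.97). For tRNA-Thr-TGT-5 3′ the group values were 42.0 and 57.0, and for tRNA-Ser-GCT-7 5′ 30.6 and 47.6, in the authors' deposited table. Both pairs lay much closer than those fold changes. For tRNA-Trp-CCA-1 3′ they were 12.7 and 42.6, and for tRNA-Gly-GCC-4 3′ 8.09 and 80.6. On the higher side of the authors' deposited table were a partial precursor row of tRNA-Gly-GCC-7-1 at 1.85 (SE 0.94), with p under 0.05, and tRNA-Lys-TTT-2 5′ at 1.77 (SE 0.94), with p above it. Of the tRX entries, tRX-Trp-NNN-1 3′ at -3.89 (SE 1.14) and tRX-Cys-NNN-55164 (neither end) at -4.06 (SE 1.30) led the lower side of the authors' deposited table, and the antisense row of tRX-Cys-NNN-102913 at 2.59 (SE 0.96) the higher side. 4 tRNA rows were higher and 46 lower at unadjusted p under 0.05. The abundant 5′ fragments stood at -0.40 (SE 0.68) for tRNA-Gly-GCC-1, -0.71 (SE 0.70) for tRNA-His-GTG-1, 0.07 (SE 0.70) for tRNA-Glu-CTC-2, 0.27 (SE 0.69) for tRNA-Glu-TTC-1 and -0.34 (SE 0.69) for tRNA-Val-CAC-2 in the authors' deposited table.

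None of these tsRNAs passed for daughter fertility either. Benjamini-Hochberg adjustment of the p-values of the authors' deposited table left 0 rows past 0.05. Unadjusted p was under 0.05 for 1311 rows, 149 higher and 1162 lower, again with 4938 expected by chance, and 1077 of the lower rows had a mean under 10. With fewer than expected, the count of 0 again does not show that no tsRNA differs. With a mean of at least 10, 43 were higher and 85 lower, and the median log2 fold change over all such rows was 0.04. No family passed, and 4 of the 140 with a p had an unadjusted p under 0.05, all lower with high daughter fertility. Their group values with high and low daughter fertility were 97.0 and 115 for 3′ Gln-TTG, 42.0 and 56.3 for 3′ Thr-TGT and 34.4 and 47.6 for 5′ Ser-GCT. These lay much closer than the model log2 fold changes of -2.46, -2.76 and -2.38. For 3′ Cys-GCA they were 24.9 and 80.1, with a model change of -2.13. The low daughter fertility libraries were the deeper ones.

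**Figure D3:**
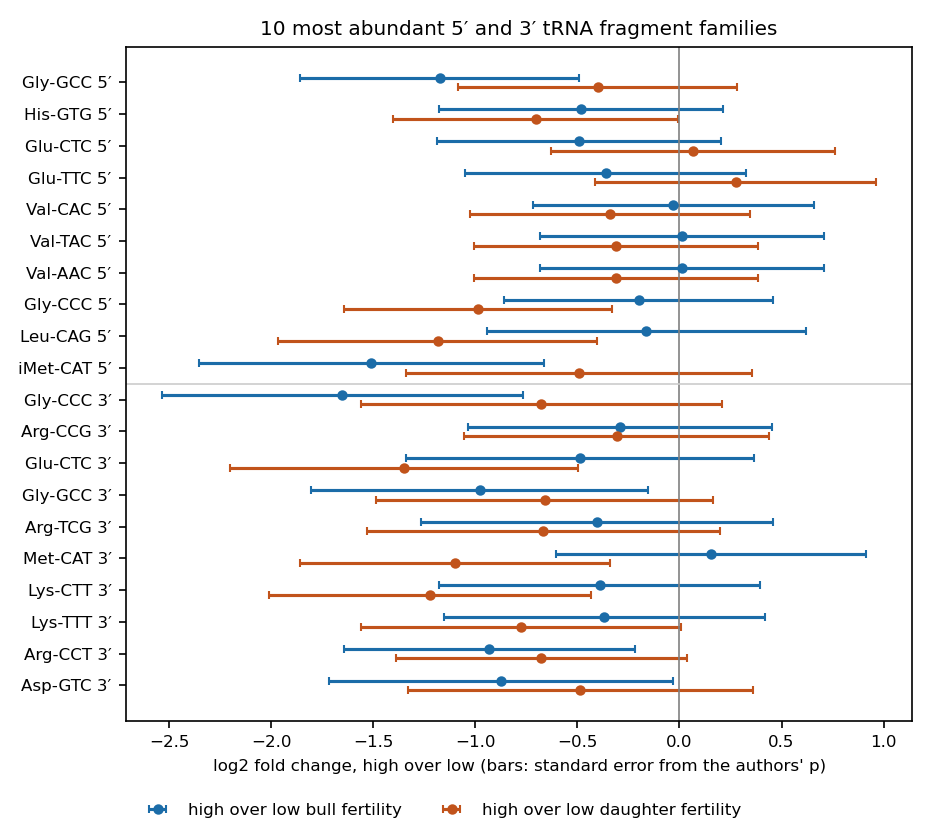
Log2 fold change (horizontal axis, high over low) of the 10 most abundant 5′ and the 10 most abundant 3′ tRNA fragment families with a p (vertical axis), in blue for bull and in orange for daughter fertility, with the standard error implied by the authors' p as bars. The 5′ fragment of Gly-GCC stands at -1.17 for bull and -0.40 for daughter fertility.

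Across the 966 miRNAs with both fold changes, the bull and daughter fertility effects had a Pearson correlation of 0.19 and a covariance of 0.17. The sign of both rests on the inferred direction for daughter fertility, and turning it gives a correlation of -0.19. Genes are not independent replicates, so no p is given. Simulated libraries with no effect that shared the same 2 libraries gave a mean correlation of 0.02 (central 95% -0.08 to 0.11) and a covariance of 0.0078. Each miRNA was drawn on its own there, so a library that moves many miRNAs at once was left out. The interval may thus be too narrow, and no conclusion on a shared effect is drawn from it. The fold changes had the same sign in 56.0% of the 966 miRNAs, or in 44.0% with the daughter fertility direction turned. The observed covariance exceeded the simulated one by 0.16. Across 140 tRNA fragment families the correlation was -0.24, against 0.01 in simulation (central 95% -0.18 to 0.18), although 67.9% of the families had the same sign in both comparisons. The simulation treated the families as separate, though some had equal values, so this interval may be too narrow as well. Above a mean of 100 in both tables the miRNA correlation was 0.26 over 226 miRNAs, with the same sign in 52.2%, or -0.26 and 47.8% with that direction turned.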

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

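The tests of the miRNAs listed at 0, of the overlap between the comparisons and of a deviating library for the tsRNAs were chosen or changed after their results had been seen. The depth and shared-read tests of the tsRNAs were set beforehand, but that their exact intervals decide was added after their values had been seen.

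Antisense rows of tRNA entries were outside the fragment families, though 352 had a p among all rows tested (under 0.05 for 0 with bull and 4 with daughter fertility). Of 367 such rows 10 exceeded 3 reads in all 4 group values, led by tRNA-Lys-TTT-27 at 137 with high and 189 with low bull fertility, and 114 with high and 65.7 with low daughter fertility, in the authors' deposited table. Whether the counting used strand is not given in the sources used here.

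11 miRNAs were listed at 0 over all bull fertility libraries and above 0 in the daughter fertility table, among them miR-2284z and miR-378. For 8 of them the mean was a whole multiple of 1 step, so all reads lay in 1 library, with 369 reads for miR-2284z. The 3 others were not whole multiples. For miR-2284z a difference shared by the low daughter fertility group is argued against, since 1 library held all its reads. Greater depth alone is also argued against for miR-2284z. At the lowest size factor its values allow, a shared library would hold about 124 reads of miR-2284z, and it had none. Several of the 8 had few reads, such as 4 for miR-2285n and 10 for miR-2284y. So few can be missed in shallower libraries, so for those a group difference, depth and a deviating library cannot be told apart. A single deviating library may account for miR-2284z, and its cause, biological or technical, was not tested.

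Of the tsRNA rows with unadjusted p under 0.05, a share of 0.886 was lower with high daughter fertility, and of 0.664 at a mean of at least 10. Among such rows with a mean of at least 100 the share lower was 0.929 (13 of 14, exact 95% interval 0.661 to 0.998), which met the bound of 0.8 set against greater depth of the low libraries, but its interval did not. Taking 1 row per family gave a share of 1 (4 of 4, interval 0.398 to 1), so near-identical rows that count the same reads stay open too. Both intervals take the rows as independent, though rows may share reads and come from the same libraries, so they may be too narrow. For 3′ families the ratio of group medians gave 0.501 of the model's median change. A value under 0.5 had been named for a single deviating low daughter fertility library, so this lay just above that bound. For 5′ families it was 0.616 and for those of neither end 0.112, for which no bound was set. Greater depth, shared reads, a deviating library and daughter fertility itself cannot be told apart, because the rows are few, the counting of shared reads is not stated, and depth follows the groups.

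6 miRNAs had an unadjusted p under 0.05 in both comparisons, 5 in the same direction: miR-2285cp, miR-365-3p, miR-2421 and miR-2385-5p higher and miR-98 lower with high fertility. With the inferred daughter fertility direction turned, 1 would be in the same direction. With the direction as inferred and p from the Wald statistic for rows without a p, it would be 9 of 10. This adds miR-323b-3p, miR-2285cn, miR-2377 and miR-6519. Each of these has no p in 1 comparison, so the authors' test may have set that row aside. For the 2 libraries shared by both comparisons, draws with no effect were first run with simulated calls by size of fold, and 70 of 100 held as many. The test was then changed to calls by fold over standard error, nearer to how the observed calls were made, and 2 of 100 draws did. The verdict turned with that change, made after the first value was seen, so shared libraries and a shared effect cannot be told apart here.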

How the results depend on the processing

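Alternatives other than the threshold of 0.1, adjustment over all miRNAs for the lists and the changes to the share of 5′ fragments were chosen after seeing the data. The count of 0 for bull fertility miRNAs, tsRNAs and families, and for daughter fertility tsRNAs and families, stayed at 0 under every alternative run. For daughter fertility miRNAs the count was 2, and 3 at a threshold of 0.1 or with p from the Wald statistic for rows without a p, which adds miR-2284z, whose reads lay in 1 library. The adjusted p of miR-323b-3p ranged from 0.00372 to 0.00724, that of miR-11999 from 0.0190 to 0.0277 and that of let-7a-5p from 0.0519 to 0.0674. Counting each list once per comparison, family lists with a member past the threshold numbered 3 when adjusted over the list alone (let-7 in both comparisons, miR-2284 and miR-2285 for bull fertility) and 0 over all miRNAs, and other-cell lists 1 and 0, since more names are then tested. The 5′ share of 55.9%, averaged over groups, was 52.0% without the most abundant row and 1.04% as a share of rows above 0. The correlation of 0.19 was 0.26 for miRNAs with a mean of at least 100; the cause was not tested. With the daughter fertility direction turned these were -0.19 and -0.26, by construction, and the miRNAs whose bull and daughter fertility effects differed numbered 11 against 0. Of miRNAs with p under 0.05 in both comparisons, 5 had the same direction, 9 with p from the Wald statistic for rows without a p, and 1 with the daughter fertility direction turned. By group medians the daughter fertility medians were -0.53 against -1.06 for 3′ families, where the cause was tested without a decision. They were -0.19 against -0.31 for 5′ and -0.048 against -0.43 for other families, where the cause was not tested. No paired analysis was possible because the columns carry no per-sample values. Not run for want of per-sample values were other normalizations and count tests, count filters, pseudocounts, leaving out samples, covariates, merged rows, length limits, the fit of all 10 samples, the estimated correlation, and other splits of the samples. The deviating library could not be left out. Depth limits low rows most, and the high daughter fertility libraries were the shallowest.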

Other observations

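The miRNAs without a p named here and the split at a mean of 1000 were chosen after their values had been seen. Of the 26 daughter fertility miRNAs with a statistic and no p, several had large fold changes. There miR-3600 stood at -10.42 (SE 3.70), with a mean of 1623 against 1.92 in the bull fertility comparison, in the authors' deposited tables. The widely expressed miR-27b stood at -5.22 (SE 1.92), miR-16b at -4.69 (SE 1.74), miR-16a at -4.66 (SE 1.94) and miR-221 at -1.93 (SE 0.93) in the authors' deposited table. On the other side, miR-33b was at 3.16 (SE 1.04) and miR-2285cn at 3.38 (SE 1.06) in the authors' deposited table. The reads of these miRNAs in each library cannot be seen here, but 1 library of each daughter fertility group also entered the bull fertility comparison. Bull and daughter fertility means were 7.54 and 170 for miR-27b, 2.98 and 92.2 for miR-16a, and 0.651 and 13.3 for miR-16b. For these and miR-3600 the shared libraries thus held few of the reads, so the change was not common to all libraries of a group. Means lay closer for miR-221 (40.3 and 104), miR-33b (37.7 and 214) and miR-2285cn (47.9 and 52.4). Of the 26, 24 were lower with high daughter fertility, which is also the direction of the 8 miRNAs whose reads lay in 1 library, 2 of which, miR-2284z and miR-378, are among the 26.

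Of miRNAs with a mean of at least 1000, 8 of 16 were higher with high bull fertility (median log2 fold change 0.01) and 17 of 24 with high daughter fertility (median 0.46). These are different sets, and the difference between them was not tested. With the inferred daughter fertility direction turned, those 17 would be lower with high daughter fertility and the median would be negative. In a test of the difference between the bull and daughter fertility effects, which ignored the shared libraries, 0 of 966 miRNAs passed and the smallest adjusted p was 0.139. That count rests on the inferred daughter fertility direction, and with it turned 11 miRNAs passed, led by miR-323b-3p.

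Since miR-323b-3p lies in a large miRNA gene cluster, the hypothesis was tested that the whole cluster moved with it, with the bounds set before the result was seen. The 51 measured names had a median log2 fold change of 0.10 for bull and -0.12 for daughter fertility. These medians lay at percentiles 85.7 and 41.1 of random lists matched on abundance. A shift of the whole cluster was thus not seen in either comparison.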
